A study of Salmo salar with 36 samples.

How the data were processed

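The series measured RNA from the olfactory organ of Atlantic salmon with 36 single-colour Agilent oligonucleotide arrays of a custom salmon design, 1 array per fish. Per the labels, the fish fall into controls and low and high hydrogen sulfide groups, each sampled at 2 and 4 weeks, with 6 fish in each of the 6 groups. The labels state neither the sulfide concentrations nor how fish were spread over tanks, so p-values measure the spread between these fish and a tank difference cannot be separated from exposure. Arrays are named here by the number in their titles.

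Each deposited scanner file holds spot intensity values on a linear scale, extracted with Agilent Feature Extraction 12.0.1.1 under protocol GE1_1200_Jun14, per the file headers. The submitters' processing notes name Agilent Feature Extraction 9.1 instead. The deposited processed intensity is already background subtracted. The authors also deposited a table of log2 values for the same arrays with 46349 rows, each centred on 0 (array medians from -0.03 to 0.03). Its rows carry no probe names and were not joined to genes, so it served only for counts of changed rows, over 39148 rows with enough values, and could not be used for gene lists. Its scaling before centring is not given in the sources used here.

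From the 43855 spots of an array, 1417 control spots and spots with an outlier mark were left out, and spots of a probe were averaged, which left 42386 probes. No spot was saturated. Processed intensities were all above 0, and were divided by each array's 75th percentile and taken to log2. Probes had to be well above background on at least 4 of the 6 arrays of at least 1 group, which kept 35508 and removed 6878. Of the kept probes 721 lacked at least 1 value, filled with group means only for gene list tests and for regrouped arrays.

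Accessions in the files were matched, without versions, to a RefSeq gene table of assembly Ssal_v3.1, used for names only. Of 40933 probes with such an accession 25641 matched, and 8297 of these had a gene symbol. Among tested probes 7463 had a symbol, over 7374 genes, so most probes that passed a test stay unnamed. Gene lists were matched by symbol and synonym alone, because the table holds no descriptions, and list sizes are small for that reason. A probe not well above background on any array of a group has only a bound there. Its fold is then given as "at least", from the bright group's mean against the higher of the dim probe's own signal and the lowest signal called above background on each array.

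Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with a mean per group was fitted to all 36 arrays, followed by contrasts, moderated statistics and Benjamini-Hochberg adjustment within each contrast at a threshold of 0.05. The 4 main comparisons set each exposed group against its own control of the same week. The others were high against low within a week, 4 against 2 weeks in controls, the change of each exposure effect between weeks, and the mean effect over both weeks. SE is the model's standard error of a log2 difference and SD the spread between fish. The model uses 1 spread per probe for all groups, so SE and p can be too small where a compared group varies more. Gene lists (31, of which 1 had under 5 members and was not tested) were tested with limma's camera at a preset correlation of 0.01, which compares a list with all other probes. Estimated correlations and fry were alternatives. Beside each list the adjusted p with an estimated correlation is given. Some list members entered through name patterns although their function differs (kinases with a ribosomal protein name, for example, and gata1 among T cell genes through a synonym). Leaving out 11 such members, a set that did not include gata1, ended no list call.

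The groups, tests, gene lists, alternative settings and the rule for named genes were fixed before the data were examined. The rule takes the 10 highest and 10 lowest named probes among those that passed, fills up with the probes of smallest p where fewer than 20 passed, and adds 4 members of each called list and all sulfide oxidation genes. In the other comparisons it takes 5 in each direction. As an exception made later, comparisons of that kind in which no probe passed name no single gene. All analyses were repeated without arrays 79 and 80 of the high 4-week group, chosen after their profiles had been seen, with 34 arrays left. The fit on 36 arrays stays the main one, as planned.

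Alternative settings were quantile normalization, median scaling, normexp background correction with an offset of 50, no filter and a stricter filter, slide as a block (13 slides, each with up to 3 arrays of different groups), title numbers that follow each other as a random block, fitting only the groups compared, a trended and robust variance model, array weights, gene means, the deposited log2 table, a wider adjusted threshold of 0.1, an unadjusted threshold with a log2 difference over 0.8, and leaving out each array in turn. The files hold no mean foreground signal, so normexp used the median signal. All arrays were scanned on 1 day, so a scan date block was not run. Title numbers are not shared between groups, so they pair no arrays across groups. Within groups they form 18 runs of numbers that follow each other, and arrays 79 and 80 form such a run. The labels do not say what these runs stand for, so fish within a run may not be independent.

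The tests were checked on simulated data built on 35508 probes for the high against control contrast at 4 weeks. With all 36 arrays, 37% of probes with a simulated log2 change of 1 and 84% with a change of 2 were recovered, and with 34 arrays 37% and 86%. Unchanged probes called numbered 7 with 36 arrays and 15 with 34. Simulated noise was independent between probes, with 1 spread per probe for all groups and no arrays apart from their group. Real arrays differ in this, so these shares need not hold for them. Array number, at 6 per group, limits the precision of every value.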

Results

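Olfactory organs of 36 Atlantic salmon were profiled, 6 each from controls, low and high hydrogen sulfide exposure at 2 weeks and the same 3 groups at 4 weeks. The title of the series places the work on the welfare of fish exposed to this gas, and the comparisons ask which genes of a mucosal and sensory tissue differ with exposure. The 75th percentile of the processed signal ran from 167 to 604 units and 63.5% to 89.0% of probes were well above background. At 4 weeks the mean 75th percentile signal was 267 ± 66.9 (SD, n = 6) in the high group, 347 ± 124 in controls and 444 ± 98.0 in the low group.

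Arrays 79 and 80 of the high 4-week group lacked much of the expression typical of the other 34 arrays. Their correlation with the median profile was 0.857 and 0.870, against 0.957 to 0.994 elsewhere, and 4919 and 5044 probes lay over 4-fold from that profile, against 46 to 2328. Several genes of olfactory neurons were far below the mean of the other 34 arrays, and the genes named here were picked after the profiles had been seen. The log2 deviations on arrays 79 and 80 were -12.51 and -5.76 for s100z (a calcium-binding protein of crypt olfactory neurons), -6.84 and -4.98 for the olfactory marker gene ompb, -6.76 and -7.25 for the odorant receptor or90a1, and -7.72 and -6.16 for the transcription factor foxg1a. Signal was not well above background for s100z and foxg1a on array 79 and for or90a1 on array 80, so those 3 values give no exact size. On the same arrays hbb was 4.89 and 4.99 higher, the transcription factor gcm2 7.15 and 7.08 higher, krt98 8.36 and 7.98 higher, and hoxa3ab 6.06 and 6.30 higher. Many values that involve the high 4-week group are therefore also given without both arrays.

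**Figure D1:**
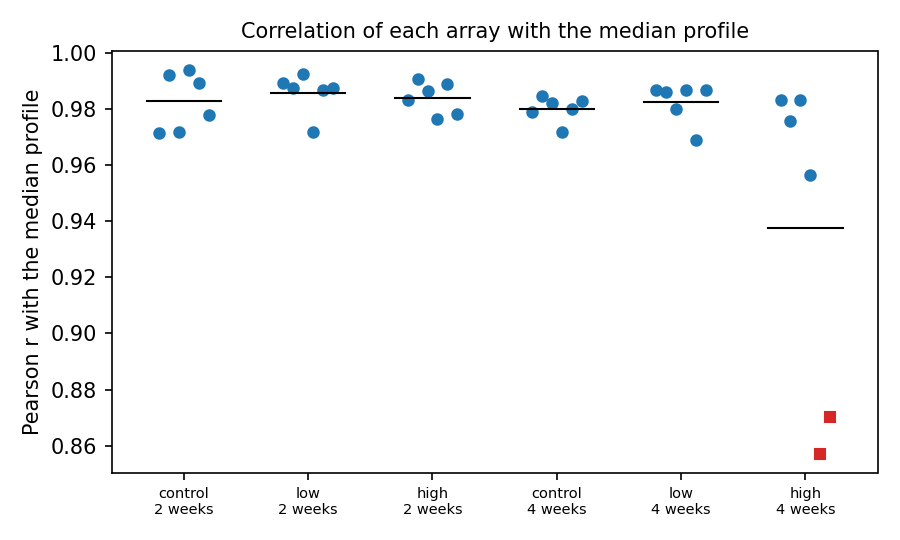
Pearson correlation of each array with the median profile over the tested probes (vertical axis, no unit), by group (horizontal axis). Circles are arrays, red squares arrays 79 and 80, and lines group means. Arrays 79 and 80 lie at 0.857 and 0.870, below the other 34, which start at 0.957.

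High exposure at 4 weeks set apart the most probes. Among genes with a role in red blood cells, hbb (a haemoglobin chain) rose by 2.72 ± 0.66 log2 (SE), from 2.23 ± 0.53 (SD, n = 6) in controls to 4.95 ± 1.84 (SD, n = 6), with an adjusted p of 0.0251, and rhag (an ammonium-transporting Rh glycoprotein) rose by 3.50 ± 0.89 (adjusted p = 0.0309). The neuropeptide precursor gene calca rose by 2.70 ± 0.50 (adjusted p = 0.0115) and nmt1b, an N-myristoyltransferase gene, by 4.01 ± 0.75 (adjusted p = 0.0115). The urea transporter gene slc14a2 rose by 3.46, the transcription factor gene lhx8a 7.98-fold, its fellow sox14 by 2.88, the noggin gene nogg3 by 2.81, and zgc:162144 by 2.61. The peptide gene cck-l was well above background on none of the 6 control arrays and at least 4.43-fold brighter in the high group, a bound that rests on arrays 79 and 80, without which cck-l did not pass (adjusted p = 0.465). Control arrays above background numbered 2 for nmt1b and 1 each for lhx8a, nogg3 and calca, so the sizes of these rises are not exact.

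The neuronal filament gene prph fell by 2.32 ± 0.64 (SE, adjusted p = 0.0420), the Notch target hes5 by 2.40 ± 0.60 (adjusted p = 0.0278) and the stathmin gene stmn1b by 1.95 ± 0.54 (adjusted p = 0.0442). The growth factor genes fgf17 and fgf1 fell by 2.12 and 1.89, the clotting factor gene f7 by 2.73, the flavin monooxygenase gene fmo5 by 1.98, rb27b by 2.21, rnf17 by 2.02 and dhx32b by 1.92. High arrays above background numbered 4 for f7, hes5, rb27b and dhx32b.

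In total, limma called 943 probes higher and 137 lower in the high group at 4 weeks, 1080 of 35508, of which 156 had a gene symbol. The split between higher and lower depended on scaling: the median of all probes was 0.15 log2 above controls, quantile normalization gave 167 higher and 121 lower, and median scaling 477 and 432. Without arrays 79 and 80, 5 probes passed, all higher: foxn4, a transcription factor gene (1.83 ± 0.34, adjusted p = 0.0447) and 4 probes with no symbol. foxn4 is named after its value was seen. The median size of the 1080 went from 1.30 to 0.90 log2 without both arrays. All 1080 kept their direction there and 988 had an unadjusted p under 0.05, but they were chosen on data that include the arrays left. Of all probes, 4246 had an unadjusted p under 0.05 there (3739 higher and 507 lower), where 1775 are expected by chance. Without both arrays nmt1b was at 2.65 (adjusted p = 0.149), calca at 2.05 (adjusted p = 0.148), hbb at 1.56 (adjusted p = 0.290), prph at -0.69 (adjusted p = 0.406) and fmo5 at -1.48 (adjusted p = 0.204). The other genes that rose were there at 1.15 (rhag), 1.47 (slc14a2), 1.02 (lhx8a), 1.08 (sox14), 1.42 (nogg3) and 1.00 (zgc:162144). Those that fell were at -0.91 (hes5, adjusted p = 0.278), -0.50 (stmn1b, adjusted p = 0.370), -0.48 (fgf17), -0.78 (fgf1), -0.65 (f7), -0.87 (rb27b), -0.53 (rnf17) and -0.56 (dhx32b), and none of these 14 passed. The count without array 79 was 2, without 80 108, without 56 170, without 55 311, without 58 467 and without 61 646. It was 2457 without 77, 4211 without 74 and 4996 without 76. With slide as a block 3463 probes passed, and 357 without arrays 79 and 80. Fewer passed with consecutive title numbers as a block (516), normexp (77), array weights (2) and only the compared groups fitted (1), and the last 2 left none of the 24 named probes that were followed with a call. Each of these 24 also lost its call when at least 1 array was left out singly. With arrays 79 and 80 the high 4-week group varied more between arrays than the other groups. The spread shared by all groups can therefore be too small for this comparison, and with it the SE and p of the 1080 calls.

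Lists of genes of the sensory epithelium lay lower at 4 weeks of high exposure. Of 61 motile cilia probes 57 were negative, with a median of -0.89 log2. The lowest p values belonged to ift172, a ciliary transport gene, at -0.84 ± 0.25 (SE), to cfap91 at -2.04 ± 0.71 and to dnal1 at -0.89 ± 0.31. None of the 61 passed alone, and camera's adjusted p was 8.09e-18, but 0.398 with an estimated correlation. Odorant receptors had a median of -1.85 over 6 probes (adjusted p = 0.00101, or 0.398 with an estimated correlation). Their members or42a4 and or90a1 were at -2.52 and -2.15. None passed over all genes tested, and 4 fell when adjusted over the list alone. Olfactory neuron signalling genes had a median of -0.92 over 6 (adjusted p = 0.0311, or 0.331 with an estimated correlation), with s100z at -2.91 and ompb at -2.08. Among 14 neuron genes the median was -0.95 (adjusted p = 0.00478, or 0.398 with an estimated correlation), and the synaptotagmin gene syt12 fell by 1.35. These 4 groups moved with arrays 79 and 80. Without them their medians were 0.16, 0.00, -0.03 and 0.08, none was called, s100z and or90a1 were at 0.16 and 0.22, and syt12 was at -0.38. Within slides, motile cilia differed by -3.55 and -3.21 in the pairs that hold arrays 79 and 80 and by -0.09, 0.04 and 0.75 in the other 3 pairs.

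Erythrocyte genes were positive for all 9 probes, with a median of 1.44 (adjusted p = 0.00101, or 0.398 with an estimated correlation, and 0.0243 by fry). hbb and rhag rose, 8 of the 9 rose when adjusted over the list alone, and hbae4 was at 1.87. On arrays 79 and 80 the list lay at 3.50 and 3.66, and on the other high arrays between 0.29 and 1.03. Without both arrays the median was 0.67 (adjusted p = 0.0801). Within slides the difference was positive in all 5 pairs, from 0.46 to 3.89.

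Metabolic and defence lists moved less. Antioxidant genes had a median of -0.11 over 23 probes (adjusted p = 0.0298, or 0.331 with an estimated correlation). Among them gclc, which makes the glutathione precursor, fell by 0.71 (adjusted p = 0.0493), and the stress regulator nfe2l2a was at -0.54. Sterol and lipid synthesis genes had a median of -0.17 over 20 (adjusted p = 0.0298, or 0.331 with an estimated correlation). The sterol enzyme gene hmgcs1 fell by 1.51, and elovl2 was at -2.73. Skeletal muscle genes had a median of -0.07 (adjusted p = 0.0298, or 0.503 with an estimated correlation), and the creatine kinase gene ckmb fell by 1.56. Without arrays 79 and 80 none of these genes passed, with gclc at -0.32, nfe2l2a at -0.42, hmgcs1 at -0.60, elovl2 at -0.47 and ckmb at -0.90. Of the 8 lists of this comparison 7 were called again with slide as a block, skeletal muscle not (adjusted p = 0.135). Quantile normalization kept 5 of the 8, and antioxidant (adjusted p = 0.464), sterol synthesis (0.117) and olfactory neuron signalling genes (0.107) lost the call. When arrays were left out singly, motile cilia, odorant receptor, neuron and erythrocyte genes stayed called each time. Antioxidant genes were not called without array 59, 61, 73 or 77 (adjusted p up to 0.236), sterol synthesis without 59, 61, 73 or 76 (0.113), olfactory neuron signalling without 59, 61 or 62 (0.0575) and muscle without 59 or 76 (0.103). Without arrays 79 and 80, camera called 10 lists, all lower and none with an estimated correlation. Camera compares a list with all other probes, and the median of all probes was 0.15 there, with the 5918 brightest at -0.10. A list of bright genes could be called lower through that shift alone, which was not tested. Of these 10, quantile normalization kept 1, cell cycle (adjusted p = 0.0121), and slide as a block kept 8. Antioxidant defence and sterol synthesis were called again. Respiratory chain genes had a median of -0.09 (adjusted p = 2.46e-05, or 0.119 with an estimated correlation), proteasome genes -0.19 (adjusted p = 0.000249, or 0.119) and cell cycle genes -0.17 (adjusted p = 6.49e-05, or 0.431). Among the members ndufb2 was at -0.37, psmd2 at -0.41 and aurka at -0.63, and none passed alone. The 5 others were endoplasmic reticulum stress (median -0.09), glycolysis (-0.07), inflammation (-0.12), myeloid genes (-0.26) and immediate early genes (-0.17), with nos2b at -1.58 and ldha at -0.85. None of these 5 was called without control array 58, with medians of -0.09 (adjusted p = 0.0607), 0.07 (0.0735), -0.02 (0.118), -0.11 (0.247) and -0.16 (0.150) in the same order. The medians of endoplasmic reticulum stress and immediate early genes hardly moved there. Without array 77 inflammation was at 0.13 (0.799). Endoplasmic reticulum stress and sterol synthesis lost the call without 73, inflammation also without 61 or 74, myeloid genes without 59, 62, 74, 76 or 77, and immediate early genes without 77. Respiratory chain, antioxidant, cell cycle and proteasome genes stayed called with each of the 10 arrays left out.

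Dim probes stood higher than bright ones in this comparison. The 5918 dimmest had a median log2 difference of 0.60, and 0.62 without arrays 79 and 80, while the 5918 brightest had -0.07 and -0.10. With quantile normalization the values without both arrays were -0.003 and -0.02. That method gives all arrays the same distribution and so removes such a shift whatever its source. The dimmest also stood at 0.25 under low exposure at 4 weeks and at -0.24 in controls at 4 against 2 weeks.

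**Figure D2:**
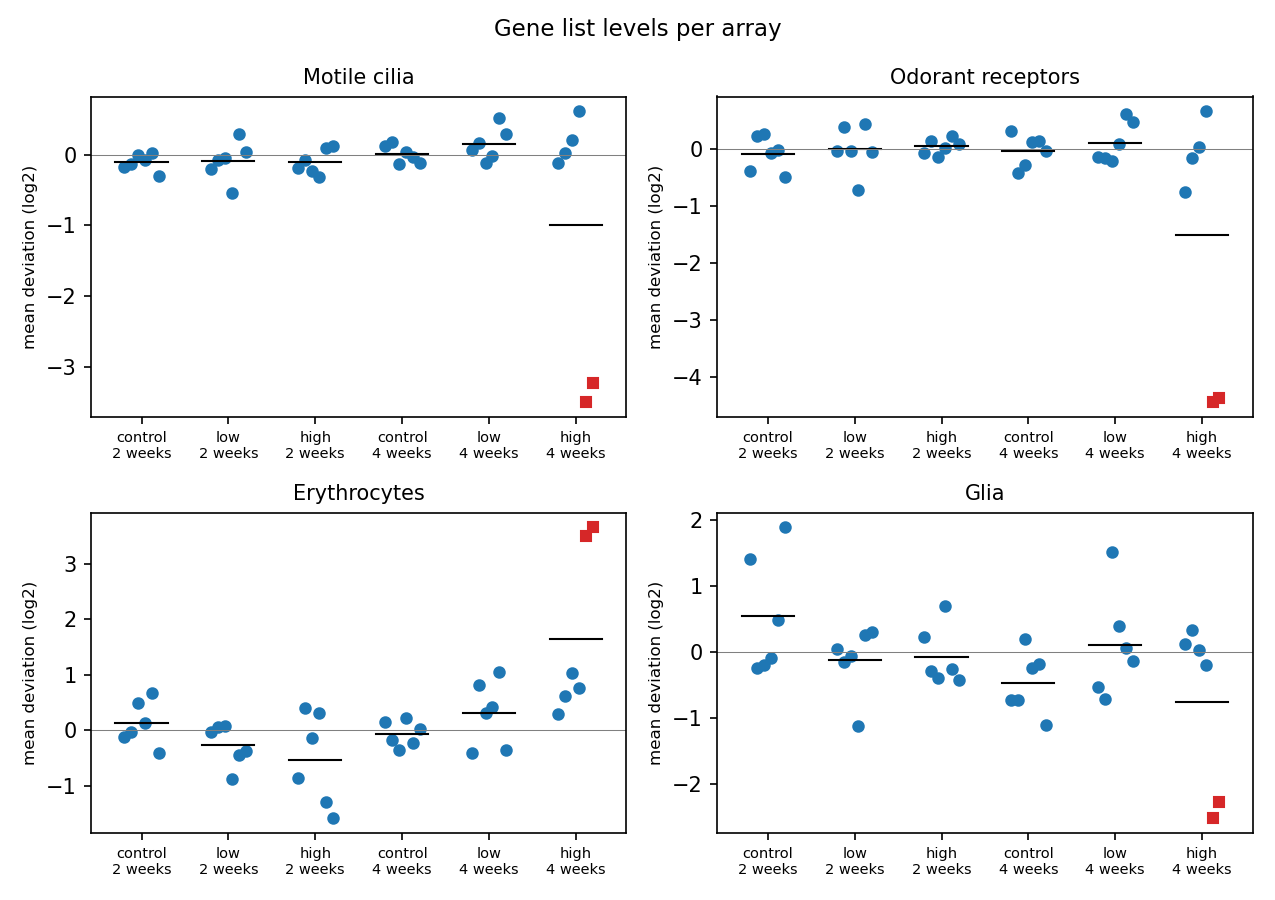
Mean log2 deviation of the members of 4 gene lists from their mean over the other 34 arrays (vertical axes), by group (horizontal axes). Circles are arrays, red squares arrays 79 and 80, and lines group means. In motile cilia, arrays 79 and 80 lie at -3.50 and -3.23, and in erythrocytes at 3.50 and 3.66.

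Low exposure at 4 weeks gave no passing probe. The ribonuclease gene ang1 had the smallest p among named genes, at -3.49 ± 0.88 log2 (SE). The opsin gene tmtops2b was at 2.16 ± 0.56, at least 1.58-fold brighter, pi15b at 3.19 ± 0.91, at least 2.99-fold brighter, and the myelin gene mbpa at 2.14 ± 0.71. The gene nmt1b, called in the high group, was at 2.28 ± 0.75. Genes of T cells and cytotoxic cells were lower as a list, with 12 of 15 probes negative and a median of -0.26 (adjusted p = 0.00343, or 0.510 with an estimated correlation). Its members foxp3b, a regulator of regulatory T cells, prf1.3, a perforin gene, and cd8a were at -0.76, -0.88 and -0.49 and did not pass over all genes tested, while 1 fell when adjusted over the list alone. The list stayed called with each of the 12 arrays left out (adjusted p up to 0.0416). Quantile normalization (adjusted p = 0.0150) and slide as a block (3.78e-05) kept the call, but neither normexp setting did. limma called 0 probes, and 1225 had an unadjusted p under 0.05 where 1775 are expected by chance. Arrays 79 and 80 widened the spread that all groups share in the fit. Without them the median SE fell from 0.286 to 0.255 and 1616 probes had an unadjusted p under 0.05. Again 0 passed, and 3 lists were called.

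High exposure at 2 weeks also gave no passing probe. The largest statistics among named genes were those of txnip, phka1b, prss35 and f5. The redox regulator txnip was at 0.75 ± 0.21 log2 (SE) and the phosphorylase kinase subunit gene phka1b at -1.65 ± 0.47. The protease gene prss35 was at -0.88 ± 0.26 and the clotting factor gene f5 at 1.07 ± 0.32. The lipoxygenase gene alox5a was at 0.73 ± 0.25 and sel1l, of protein quality control, at 0.65 ± 0.21. Ribosomal protein genes were higher as a list by a median of 0.09 over 48 probes (adjusted p = 0.00393, or 0.834 with an estimated correlation), with rpl11 at 0.57. Cell cycle genes were lower by list, with a median of -0.17, 31 of 36 probes negative (adjusted p = 0.00725, or 0.834) and ccnb2 at -0.38. Erythrocyte genes had a median of -0.88 (adjusted p = 0.0160, or 0.834), with hba at -1.14 and alas2 at -1.35. Glia genes had a median of -0.43 (adjusted p = 0.0249, or 0.834), with the myelin gene mpz at -1.08. limma called 0 probes, with 1121 at an unadjusted p under 0.05 (0 and 1523 without arrays 79 and 80). Without control arrays 28 and 35, which had the highest glia levels of the 2-week arrays, the glia median was -0.07 (adjusted p = 0.839) and the cell cycle list was not called (median -0.19, adjusted p = 0.0682). Neither was called with slide as a block (adjusted p = 0.169 for both), while erythrocyte and ribosomal genes were. Quantile normalization left ribosomal genes at 0.03 (adjusted p = 0.618), and the other 3 lists were called. Single arrays mattered: ribosomal genes lost the call without 31 or 53 (adjusted p up to 0.163), cell cycle without 28 or 53 (0.169), erythrocytes without 34, 52 or 53 (0.147) and glia without 28, 35, 47, 52 or 53 (0.492).

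Low exposure at 2 weeks gave no passing probe either. f5 was at 1.15 ± 0.32 log2 (SE), close to its value in the high group, which shares the controls. The growth factor receptor-like gene pgfrl was at -1.30 ± 0.37, the homeobox gene barx1 at -1.46 ± 0.42, gpx7, a glutathione peroxidase, at -0.61 ± 0.20, and il17d, a cytokine, at -1.27 ± 0.45. Extracellular matrix genes had a median of -0.32 over 28 probes (adjusted p = 0.0382, or 0.716 with an estimated correlation), with the collagen gene col1a1a at -0.84 and thbs2a at -1.09. Glia genes had a median of -0.55 (adjusted p = 0.0382, or 0.716), with mbpa at -1.35. limma called 0 probes, with 937 at an unadjusted p under 0.05 (0 and 1290 without arrays 79 and 80). Without control arrays 28 and 35 neither list was called, with medians of -0.24 (adjusted p = 0.253) and -0.19 (adjusted p = 0.845). The same held with slide as a block (adjusted p = 0.586 and 0.847), where the glia median was -0.01 and 5 other lists were called. Matrix genes also lost the call without array 29, 35, 38, 40, 41 or 44 alone, and glia without 28, 35, 38, 40 or 41 (adjusted p up to 0.282 for both).

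Among probes with a gene symbol, those of sulfide oxidation were sqor, the mitochondrial enzyme that oxidises sulfide, suox, which oxidises sulfite, and the sulfurtransferase genes tstd1 and tstd3. None of the 4 passed over all genes tested in any main comparison. The lowest p was that of tstd1 under high exposure at 4 weeks, at -0.50 ± 0.17 log2 (SE), 3.50 ± 0.26 (SD, n = 6) against 4.00 ± 0.09 in controls (adjusted p = 0.0821). It fell when adjusted over the list alone, but not without arrays 79 and 80, where it was at -0.40. In the same comparison sqor was at 0.58 ± 0.35 and suox at 0.36 ± 0.26, or -0.18 and -0.11 without both arrays, and tstd3 was at -0.12 ± 0.18. At 4 weeks of low exposure the values were 0.04 for sqor, 0.06 for suox, -0.14 for tstd1 and 0.03 for tstd3. At 2 weeks they were 0.31, 0.15, 0.09 and 0.13 under low exposure and 0.09, 0.10, 0.06 and -0.19 under high exposure, in the same order. The list was too short for a list test.

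High and low exposure were set against each other to ask for effects of dose. At 4 weeks ttr, the transthyretin gene, was higher in the high group by 1.77 ± 0.34 log2 (SE, adjusted p = 0.0419), zfp36l1a, an RNA-binding regulator, by 2.00 (adjusted p = 0.0434), prr35 by 1.13 and tatdn2 by 1.00, ppfibp1b was 0.72 higher, and slc35a1, a sialic acid transporter gene, was lower, at -1.13 ± 0.23. None of these passed without arrays 79 and 80, where ttr was at 1.91 (adjusted p = 0.143), zfp36l1a at 1.09, prr35 at 1.15, tatdn2 at 0.79, ppfibp1b at 0.63 and slc35a1 at -0.73. Each of these 6 also lost its call without at least 1 single array. Motile cilia genes were lower by list, with 57 of 61 negative and a median of -1.12 (adjusted p = 3.45e-21, or 0.408 with an estimated correlation), but the median was -0.01 without arrays 79 and 80 (adjusted p = 0.189). limma called 79 probes higher and 7 lower, and 0 without both arrays (3095 at an unadjusted p under 0.05). Left out singly, arrays 65, 67, 68 and 79 gave 0, array 80 1, 64 8, 70 139, 73 751, 77 1418, 74 2639 and 76 3028, and with slide as a block 0 passed. At 2 weeks limma called 0 probes, with 1092 at an unadjusted p under 0.05 (0 and 1407 without arrays 79 and 80). Cell cycle genes were lower in the high group by list there (median -0.19, adjusted p = 0.000265, or 0.992 with an estimated correlation), but not with slide as a block (adjusted p = 0.139). Low array 41 carried that difference, and without it the median was -0.05 (adjusted p = 0.410).

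The change of the high effect between 2 and 4 weeks was tested directly. nmt1b changed by 5.30 ± 1.06 log2 (SE, adjusted p = 0.0483), and hbb was at 3.97 ± 0.93, phka1b at 2.89 ± 0.67 and calca at 2.99 ± 0.71, each with an adjusted p of 0.0663. For nmt1b and calca few 4-week control arrays were above background, so their sizes are not exact. Erythrocyte genes differed between weeks by a median of 2.58 (adjusted p = 6.41e-05, or 0.656 with an estimated correlation, and 0.0253 by fry), and by 1.41 without arrays 79 and 80 (adjusted p = 0.00662, or 0.426). limma called 37 probes, all higher at 4 weeks, and 0 without arrays 79 and 80 (4043 at an unadjusted p under 0.05), where nmt1b was at 3.94 (adjusted p = 0.139). Left out singly, arrays 29, 31, 34, 46, 52, 53, 55, 56, 77, 79 and 80 gave 0, arrays 35, 49, 58 and 61 2, and array 32 13. Counts were 64 without 28, 92 without 73, 106 without 47, 111 without 62, 115 without 50, 329 without 59, 452 without 74 and 804 without 76. With slide as a block 821 passed, and with consecutive title numbers as a block 0, where nmt1b had an adjusted p of 0.0826. It also lost the call without single arrays (adjusted p up to 0.102). For the change of the low effect no probe passed (0 by limma, with 1853 at an unadjusted p under 0.05). Without arrays 79 and 80 these counts were 0 and 2421. By list, glia genes were 1.13 higher in that change (adjusted p = 0.0184, or 0.415 with an estimated correlation). Without control arrays 28 and 35 the value was 0.45 (adjusted p = 0.403), and with slide as a block 0.28 (adjusted p = 0.645). The call was also lost without array 28, 35, 62 or 67 alone (adjusted p up to 0.0945).

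Between controls at 4 and 2 weeks no probe passed (0 by limma). At an unadjusted p under 0.05 there were 1986 probes, or 2696 without arrays 79 and 80, where again 0 passed. Glia genes were lower at 4 weeks by list, with a median of -1.13 (adjusted p = 0.000938, or 0.496 with an estimated correlation), and proteasome genes higher, at 0.15 (adjusted p = 0.0210, or 0.607). Without control arrays 28 and 35 glia genes were at -0.69 (adjusted p = 0.397) and proteasome genes at 0.16 (adjusted p = 0.0133). All 6 lists called here lost the call with slide as a block, with adjusted p of 0.182 for glia and 0.403 for proteasome genes. With arrays left out singly glia stayed called, and proteasome genes were not without 31, 35, 59 or 61 (adjusted p up to 0.152). Averaged over both weeks, limma called 0 probes for high exposure (3525 at an unadjusted p under 0.05) and 0 for low exposure (461). Without arrays 79 and 80 the unadjusted counts were 2083 and 626. Without arrays 79 and 80, 1 unnamed probe passed for high exposure, at 1.74 ± 0.29. The antioxidant list was lower over both weeks of high exposure and was the one list called with an estimated correlation, with a median of -0.12 over 23 probes (adjusted p = 0.00184, or 0.0356 with an estimated correlation). Of its probes 15 were negative and none passed alone, and fry's adjusted p was 0.116. Its median was again -0.12 without arrays 79 and 80, with 19 probes negative (adjusted p = 1.45e-05, 0.0109 with an estimated correlation and 0.178 by fry). It stayed called with each of the 24 arrays left out (adjusted p up to 0.0157).

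Low and high exposure share their controls within a week. At 2 weeks 67.1% of probes differed in the same direction in both comparisons, where simulated unchanged groups gave 66.99% ± 6.09 (SD, 100 draws) and controls split between both comparisons gave 46.8%. At 4 weeks the share was 62.5%, and 52.8% with split controls, or 66.3% and 52.7% without arrays 79 and 80. The covariance of the log2 differences across probes, which are not independent replicates, was 0.0507 at 2 weeks and 0.0746 at 4 weeks (0.0705 without both arrays), against a simulated 0.0586 ± 0.0237 (SD). No probe was called in both.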

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

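The tests on arrays 79 and 80, on dim probes and on control arrays 28 and 35 were chosen only after the result was seen. Among 222 tests for a single array apart from its group, 14 crossed the limit, and chance flags about 1 in 20 (11.1 here). At 2 weeks, control array 35 stood at -0.14 log2 for antioxidant genes and -0.50 for olfactory neuron signalling, and control array 28 at -0.67 for mucus genes. Array 41 of the low group stood at -0.23 for heat shock genes, -0.81 for olfactory neuron signalling, -1.13 for glia, 0.51 for interferon genes, 0.90 for myeloid genes and, in its own level, -2.88 for sqor. High array 49 stood at 0.59 for cartilage and bone genes. At 4 weeks, control array 58 stood at 0.33 for glycolysis genes, control array 56 at -0.32 for epithelial junctions, and low arrays 65 and 64 at 0.39 for inflammation and 2.11 for skeletal muscle.

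Effects that differed between weeks were the 37 probes of the high effect, and its odorant receptor (-1.72), motile cilia (-0.88) and erythrocyte (2.58) lists. None of these lists was called with an estimated correlation (smallest adjusted p = 0.656), and fry called erythrocyte genes (0.0253). Without arrays 79 and 80 no probe passed. Of these lists only erythrocyte genes then kept the call, and motile cilia genes turned direction. For the low effect they were glia (1.13), complement (0.74), T cell (-0.23) and extracellular matrix genes (0.43). No list of that change was called with an estimated correlation (smallest adjusted p = 0.415) or without control arrays 28 and 35 (0.141). With slide as a block only T cell genes among these were called again (adjusted p = 0.00075), and complement genes turned to -0.18.

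Arrays 79 and 80 have title numbers that follow each other, and the labels do not say whether such neighbours shared a tank. Several olfactory genes were far lower on both arrays. Low signal did not account for it, since 4 of 4 signal measures lay inside the range of the other 34 arrays. These measures do not assess RNA quality, which was not tested. Loss of olfactory cells alone, with all other cells kept alike, would leave erythrocyte genes near epithelial and matrix genes. They lay 3.66 and 3.81 log2 above these, against at most 1.13 elsewhere, which does not match that narrow form. The test replaced, after values had been seen, one on gill markers (2.46), so its outcome was known beforehand. It cannot exclude loss of olfactory cells together with more blood, which was not tested. Tissue such as gill could be the source. A gill list written after genes such as gcm2 were seen had a median of 2.70 on the lower array, beside blood at 3.72. Its 9 markers not seen before had a median of -0.43. Neither gill median can decide, because both include 5 other potassium channels taken in by a name pattern, all 5 among those 9 markers. Of the 4 proper ones there, rhbg and kcnj1b were above background on only 4 of the other 34 arrays each, so kcnj1b had no room to fall. On arrays 79 and 80 rhbg lay 10.98 and 11.72 higher, a rise with no exact size. There slc12a2 was at 0.94 and 1.67 and slc9a2 at -0.43 and -0.51. Exposure, dissection, RNA quality and sample identity thus stay open as sources, with 8 other tissue lists between -0.79 and 0.34 and 11 of 68 hox probes above all other arrays.

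Dim probes were higher in the high group at 4 weeks, by 0.62 log2 without arrays 79 and 80, where the standard error from array means is 0.37. Distortion of array 77 alone would leave no shift without it, and 0.25 was left (standard error 0.18), too close to that spread to decide. Under low exposure at 4 weeks the shift was also 0.25, or 0.20 with brightness ranked on the 34 arrays. The other shifts given here rest on a ranking by the 4-week controls, which alone tends to raise dim probes against them. For array brightness the correlation with dim-probe level over 34 arrays was -0.20 (permutation p = 0.245), 0.08 by rank and 0.22 without the 2 farthest arrays, so a relation was neither shown nor excluded. A rise of weakly expressed genes was not tested apart from these. Quantile normalization, where the shift was -0.003, removes it whatever the source and cannot decide.

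Glia genes were lower in both exposed groups at 2 weeks, and matrix genes in the low group. Of these 3 list calls 0 were kept without control arrays 28 and 35, but both arrays were picked for their high glia level (1.41 and 1.89), so this cannot decide whether more nerve or connective tissue in them is the source. Matrix level was high on array 35 (0.63) but not on array 28 (-0.23), and the matrix median without both moved from -0.32 to -0.24. An effect of exposure stays open too. The glia medians left were -0.07 for high and -0.19 for low, and the direction against all other probes turned in both. The choice of arrays shrinks these medians by itself, so they cannot decide on exposure either.

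Arrays were also regrouped at random, with 100 groupings per contrast, the real one included. For high exposure at 4 weeks 6 of 100 had as many calls as the real 1091 (highest other 3820), so chance cannot be excluded, and without arrays 79 and 80 it was 17 of 100 (real 5, highest other 242). For high against low at 4 weeks it was 4 (real 86, highest other 1200) and for the change of the high effect 2 (real 46, highest other 255), each under 1 in 20. Chance stays hard to exclude for both, since 12 counts were tested this way, groupings ignored the slides, slide as a block gave 0 and 821 calls, and both had 0 without arrays 79 and 80. For the 8 contrasts with 0 real calls it was 100 of 100, an outcome fixed by the 0 that says nothing about chance, with highest others of 0 for low and for high at 2 weeks, 7 for low at 4 weeks, 1 for high against low at 2 weeks, 2 for controls, 0 for the change of the low effect, 77 for high and 1 for low over both weeks.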

How the results depend on the processing

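Leaving out arrays 79 and 80, control arrays 28 and 35, single arrays in list tests or list members that do not belong, replacing extreme local backgrounds, and all settings on the 34 arrays were chosen after the result was seen. Of the values tested, 2335 for named genes and lists kept direction and side of the threshold, 555 kept direction but lost the call, 121 kept direction and gained it, and 89 turned. The cause was not tested except where given. Without arrays 79 and 80, counts were 5 for high at 4 weeks, 0 for high against low at 4 weeks, 0 for the change of the high effect and 1 for high over both weeks. With quantile normalization, counts were 288 for high at 4 weeks, 0 for the change of the high effect and 1 for high at 4 weeks on the 34 arrays. With scaling to the median, counts were 3 for high against low at 4 weeks and 0 for the change of the high effect. With normexp, counts were 21405 for low at 4 weeks, 77 for high at 4 weeks, 5 for high against low at 4 weeks, 13 for the weeks in controls, 19 for the change of the high effect and 0 for high at 4 weeks on the 34 arrays. With normexp after replacing extreme local backgrounds, counts were 2151 for high at 4 weeks, 16370 for high against low at 4 weeks, 0 for the change of the high effect and 0 for high at 4 weeks on the 34 arrays. With no filter, counts were 6 for high against low at 4 weeks and 1 for the change of the high effect. With probes above background on all arrays, counts were 567 for high at 4 weeks, 41 for high against low at 4 weeks and 0 for high at 4 weeks on the 34 arrays. With slide as a block, counts were 3463 for high at 4 weeks, 0 for high against low at 4 weeks, 821 for the change of the high effect and 357 for high at 4 weeks on the 34 arrays. With consecutive title numbers as a block, counts were 516 for high at 4 weeks, 6 for high against low at 4 weeks, 0 for the change of the high effect and 17 for high at 4 weeks on the 34 arrays. With only the compared groups fitted, counts were 1 for high at 4 weeks, 0 for high against low at 4 weeks, 1 for the change of the high effect, 1 for high over both weeks and 2 for high at 4 weeks on the 34 arrays. With a trended and robust variance, counts were 36 for high against low at 4 weeks, 16 for the change of the high effect and 1 for high at 4 weeks on the 34 arrays. With array weights, counts were 2 for high at 4 weeks, 0 for high against low at 4 weeks, 2 for the weeks in controls, 2 for the change of the high effect, 2 for high over both weeks and 0 for high at 4 weeks on the 34 arrays. At an adjusted threshold of 0.1, counts were 3735 for high at 4 weeks, 1175 for high against low at 4 weeks, 453 for the change of the high effect and 25 for high at 4 weeks on the 34 arrays. At an unadjusted p under 0.05 with a log2 difference over 0.8, counts were 360 for low at 2 weeks, 413 for high at 2 weeks, 602 for low at 4 weeks, 5137 for high at 4 weeks, 524 for high against low at 2 weeks, 4373 for high against low at 4 weeks, 803 for the weeks in controls, 4915 for the change of the high effect, 1262 for the change of the low effect, 904 for high over both weeks, 94 for low over both weeks and 2150 for high at 4 weeks on the 34 arrays. In the deposited log2 table, counts were 414 for high at 4 weeks, 247 for high against low at 4 weeks, 0 for the change of the high effect and 0 for high at 4 weeks on the 34 arrays. List calls over the main comparisons numbered 15, and 0 with an estimated correlation, 1 with fry and 26 with normexp. Of the sulfide oxidation genes, 1 was called under either normexp setting. With controls split between comparisons, 46.8% of probes at 2 weeks and 52.8% at 4 weeks shared a direction. Leaving out 1 array at a time gave 2 to 4996 for high at 4 weeks, 0 to 3028 for high against low at 4 weeks, 0 to 804 for the change of the high effect, 0 to 6 for high over both weeks (6 without array 76, 1 without 80) and 0 to 0 for every other contrast. On the 34 arrays high at 4 weeks gave 1 to 124: 1 without 56, 58 or 77, 3 without 55, 8 without 73, 11 without 59 or 61, 13 without 74 and 124 without 76. Normexp failed through its own fit: single spots reached net signals of -157087 and -100573 on control arrays 59 and 61, fitted background means were -959 and -803, and correlations with the main values fell to 0.733 and 0.615. After the repair, the offset of 50 tied the level of dim probes to array brightness (r = -0.98 over 34 arrays), 5629 of the 5918 dimmest probes were called for high against low at 4 weeks, and removal of the offset left 1948 calls there and 3318 for high at 4 weeks.

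Values that turned follow as log2, where for lists the direction is that against all other probes. Without control arrays 28 and 35, low at 2 weeks gave glia genes -0.19. High at 2 weeks gave glia genes -0.067. With normexp, high at 4 weeks gave antioxidant genes 0.19, nogg3 -0.070, calca -0.39, gsr 0.039, tstd3 0.013 and sqor -0.32. High against low at 4 weeks gave ribosomal genes 0.053. The weeks in controls gave mucus genes -0.13, ribosomal genes -0.43 and proteasome genes -0.37. High over both weeks gave antioxidant genes 0.089 and cell cycle genes -0.12. High at 4 weeks on the 34 arrays gave respiratory chain genes 0.29, antioxidant genes 0.17, endoplasmic reticulum stress genes 0.21, glycolysis genes -0.063, cell cycle genes -0.18, inflammation genes -0.31, myeloid genes 0.32, immediate early genes -0.12 and proteasome genes 0.26. High at 2 weeks gave sqor -0.045. Low at 4 weeks gave tmtops2b -1.09, mipa -1.25, crhbp -1.22, pi15b -0.38, kbrs2 0.018, pla1a -0.80, dlk1 -1.06, elf3 0.057, tgfb5 -1.09, tdrd12 -0.91, nmt1b -0.70, mbpa -0.68, sqor -1.04 and tstd1 0.57. The change of the high effect gave ttc38 -0.25, nemp2 -0.034, phka1b -0.16, calca -0.30 and arhgap36 -0.34. Without arrays 79 and 80, high at 4 weeks gave motile cilia genes 0.16, or90a1 0.22, s100z 0.16, cnga4 0.042, ompa 0.41, sqor -0.18 and suox -0.11. The change of the high effect gave motile cilia genes 0.10. High over both weeks gave motile cilia genes 0.090. With normexp after replacing extreme local backgrounds, high against low at 4 weeks gave ribosomal genes 0.089. The weeks in controls gave ribosomal genes 0.066 and proteasome genes 0.084. Low at 2 weeks gave arhgap36 0.040, ehd2a 0.020 and stard8 0.016. Low at 4 weeks gave tmtops2b -0.075, mipa -0.24, crhbp -0.21, dlk1 -0.10, tgfb5 -0.10, tstd3 -0.19 and sqor -0.22. High at 4 weeks gave cnga4 0.048, ompa 0.055 and mb 0.030. With slide as a block, the weeks in controls gave complement genes 0.12. The change of the low effect gave complement genes -0.18. Low at 2 weeks gave fabp7 0.10 and suox -0.17. With array weights, low at 2 weeks gave sqor -0.084 and tstd1 -0.11. High at 2 weeks gave sqor -0.14 and tstd1 -0.12. Low at 4 weeks gave tstd3 -0.060. With each array left out in turn, low at 2 weeks gave suox -0.023 to 0.32 and tstd1 -0.051 to 0.21. High at 2 weeks gave sqor -0.040 to 0.19 and tstd1 -0.084 to 0.18. Low at 4 weeks gave tstd3 -0.11 to 0.10, sqor -0.081 to 0.12 and suox -0.020 to 0.18. High at 4 weeks on the 34 arrays gave inflammation genes -0.15 to 0.13. With scaling to the median, low at 4 weeks gave tstd3 -0.020 and sqor -0.0064. With quantile normalization, low at 4 weeks gave sqor -0.089. The scan date block was not run, as all arrays were scanned on 1 day. Signal limits dim genes: 63.5% to 89.0% of probes were well above background on an array. Signals of the rest give no exact level, although those of kept probes entered the fits as they were.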
